A study of Mus musculus with 6 samples.

How the data were processed

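The series describes single-cell libraries from the infarcted hearts of female C57Bl6/J mice, a common inbred laboratory strain, collected 5 days after the left anterior descending coronary artery was tied off for good. Per the labels, young animals were 3 to 5 months old and old animals 15 to 17 months old. Its 6 samples are 2 ages with 3 library types each: gene expression, antibody-derived tags and hashtag oligonucleotides, with 1 sample per age and library type. Antibody-derived tags are antibodies carrying a DNA label, so that a surface protein is read together with the RNA of a droplet. Hashtags are antibodies whose DNA label marks the animal a cell came from. Per the labels' protocols, 3 animals per age were hashtagged and pooled, and libraries were made with droplet chemistry version 3.1 for the 3' ends of transcripts. The protocol calls the input cells in one place and gives a single-nucleus library name in another, which leaves open which of these was loaded.

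Cell Ranger 7.0.0 and Seurat 4.1.0, with the builds mm10 and GRCm38.p4, are named in the submitters' processing notes. The mapping, filtering and cell-calling settings are not given in the sources used here. The files analysed were, as deposited by the authors, the barcode list and the feature table of 2 unfiltered matrices, numbered 3 and 4. They hold text only: 16-base droplet barcodes with the suffix 1, and an identifier, a name and a type for each matrix row. Matrix values, meaning the number of molecules per gene and droplet, were not analysed here. Library depth, cell numbers, cell types and expression levels are therefore unknown here, and a listed barcode is not a cell. The numbers 3 and 4 match no label, so neither list was assigned to an age, and young and old were not compared. The planned test of counts summed per hashtagged animal was not run for the same reasons. No per-sample column of values was left unused (0 columns).

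The lists were read with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Barcodes were matched exactly over all 16 bases. Shares carry 95% Wilson intervals, which cover counting error only. The size of the barcode pool that 2 independent random draws would imply was computed with Chapman's form of the Lincoln-Petersen estimate. For each kind of base change, the share of listed barcodes whose changed copy was in the same list was set against the share whose copy was in the other list. The geometric mean of this ratio over both libraries removes the effect of list size only under a condition. Each barcode's chance of being listed must differ between the libraries by the same factor. The standard error of this mean came from a jackknife over 64 blocks set by bases 1 to 3. Base positions were counted from 1 at the first base listed. The procedure was tested on simulated lists from 200000 barcode pairs. There the estimated number of pairs was off by 0.07% when partners were drawn independently. It was off by 0.23% when a partner was listed only with its main barcode. The ratio was 0.992 and 1.433 in these cases. The simulated pairs differed by complemented bases 8 and 9. Neither the pool estimate from single barcodes nor the ratio for single-base neighbours was tested on the simulated lists.

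Gene rows were matched by Ensembl gene identifier, without its version, to GENCODE release M21, an annotation of the same assembly (GRCm38). Positions, strands and exons come from M21, not from the annotation the authors used, whose release is not given in the sources used here. Bases that exons of other listed genes share with a named gene were summed per partner gene, so a base under 2 partners counts for each. The 382 listed mouse genes that M21 does not hold have no position here and were not checked for overlap. The lists of genes to be named were fixed before the data were examined. They were the genes of X inactivation, X-linked genes known to escape it, X-linked immune genes, genes of the antibody targets, and markers of 11 cell types (T, B, NK, macrophage, neutrophil, dendritic, fibroblast, endothelial, mural, cardiomyocyte and erythrocyte). All members were looked up by exact symbol. One antibody target and its gene are not reported here by name. Alternatives changed which barcodes were compared and how features and symbols were counted.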

Results

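The series concerns X inactivation and lymphocytes in the remodelling heart, and its design sets young against old female mice 5 days after infarction. Deposited lists of both kinds were examined for each of 2 unfiltered droplet libraries, numbered 3 and 4: the genes, antibodies and hashtags that the matrices could hold, and the droplet barcodes. Neither number could be tied to an age by the labels. The libraries were therefore described side by side and not as young and old, and no statement on expression or cell types was made. The lists carry no molecule numbers, so the depth per sample is unknown.

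The first question was which genes of X inactivation and of the lymphocyte compartment the libraries could measure. Both libraries used 1 identical feature table of 48452 rows, with 48443 gene rows, 6 antibody rows and 3 hashtag rows. Of the 78 genes fixed in advance, 76 were listed under their symbol, and none of the listed symbols stood on more than 1 row. The remaining 2 were listed under other names. Trgc1, the T cell receptor gamma constant region, was listed as Tcrg-C1 (ENSMUSG00000076749.2). Tasl, an adaptor in endosomal Toll-like receptor signalling, was listed as 5430427O19Rik (ENSMUSG00000025058.4). A listed gene is one that could have been counted, and its level was not examined.

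All 9 genes of the X inactivation list had a row, and 5 of them lie on the X chromosome. Xist, the RNA that coats the inactive X (ENSMUSG00000086503.3), is a long non-coding gene on the minus strand of chromosome X from 103460366 to 103483254 (GRCm38). Its antisense repressor Tsix (ENSMUSG00000085715.2) spans 103431517 to 103484957 on the plus strand, and thus runs across the whole of Xist. Summed per partner gene, exons of listed antisense genes (Tsix, Gm26992 and Gm27520) shared 2492 bases with Xist exons, 13.9% of its 17946 exonic bases. Here and below, a base under 2 partners counts for each, so such sums may exceed the bases covered. Overlap with listed genes that M21 does not hold was not checked. Xist exons shared 1980 bases with Tsix, 32.6% of the 6077 exonic bases of Tsix. How the authors' counting treated strand is not given in the sources used here, so whether this sharing affects counts of the pair is unknown. Jpx, an activator of Xist, lies at 103493556 to 103565696 on the plus strand, and Ftx at 103560907 to 103623790 on the minus strand. The autosomal members Spen, Hnrnpu, Ciz1 and Lbr, whose proteins act in Xist silencing or localisation, were on chromosomes 4, 1, 2 and 1. Of the 9 genes, 5 shared exonic bases with a listed gene on the same strand and 7 with one on the opposite strand. Same-strand sharing came to 431 bases in Tsix (7.09%), 633 in Ftx (6.20%), 408 in Jpx (4.66%), 194 in Xist (1.08%) and 69 in Lbr (1.45%). Antisense sharing outside the Xist and Tsix pair came to 440 bases in Lbr (9.24%), 728 in Ciz1 (8.46%), 804 in Hnrnpu (6.93%), 420 in Ftx (4.12%) and 41 in Spen (0.291%). Rlim, a ubiquitin ligase that promotes Xist expression, was the 1 member with neither.

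All 6 X-linked genes chosen as known escapees of inactivation were listed. Kdm6a and Kdm5c, which encode histone demethylases, the translation factor gene Eif2s3x, the RNA helicase gene Ddx3x and Pbdc1 had no exonic overlap with another listed gene. Utp14a shared 473 bases (11.5% of its exonic bases) with the antisense gene 9530027J09Rik. Of the 10 X-linked immune genes, 9 were listed by symbol and Tasl by its other name. Tlr7, a sensor of single-stranded RNA, lies at 167304929 to 167330558 and Tlr8 at 167242696 to 167264329, both on the minus strand of chromosome X. Neither overlapped exons of another listed gene, nor did Cd40lg, Cxcr3, Btk or Was. Foxp3, the lineage factor of regulatory T cells, shared 853 bases (18.6%) with the same-strand gene Flicr. It shared a further 1229 bases (26.9%) with antisense genes. Il2rg, the common gamma chain of interleukin receptors, shared 728 of its 2387 exonic bases (30.5%) with the same-strand gene Gm20489. The kinase gene Irak1 shared 141 bases (2.99%) with 2 microRNA genes on its strand. Reads that fall only on bases shared on 1 strand cannot be given to 1 gene. Counts of Foxp3, Il2rg and the X inactivation genes with such bases could therefore be uncertain in part. Whether the shared bases lie near the 3' ends that these libraries read was not examined. Overlap within introns was not examined either.

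The antibody rows included CD3, the gamma delta T cell receptor, NK1.1, CD44 and CD8A, which are surface proteins that tell T cell subsets and NK cells apart. The genes of these targets were listed: Cd8a, Cd44, Klrb1c (NK1.1), Trdc and Tcrg-C1 (the gamma delta receptor) and Cd3e. Klrb1c shared 413 bases (13.9%) with Gm44511 on its strand, and Trdc 303 bases (7.84%) with antisense genes. The antibody rows bore the reagent name TotalA and the hashtag rows the name TotalSeqB. Hashtags 2, 3 and 4 were present, 1 for each of the 3 animals per age that the protocol describes. All 49 markers of the 11 cell types were listed. Among them, exonic overlap on the same strand was found for Klrb1c and for the fibroblast gene Pdgfra (30 bases, 0.299%). Antisense overlap was found for Pdgfra, the cardiomyocyte gene Ttn and the erythroid gene Alas2, with 6.21%, 0.388% and 15.5% of exonic bases. Alas2, which encodes the first enzyme of erythroid heme synthesis, was the X-linked member of the marker lists.

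Coverage of the assembled X chromosome was close to complete. Of 2614 genes that GENCODE M21 places on it, 2611 had a row, as did all 948 of its protein-coding genes. Genes that M21 places on scaffolds, none of which had a row, were counted with no chromosome. Any X-linked genes among them are not in these numbers. All 1570 genes of chromosome Y were listed as well, although the animals were female. The autosomes differed from each other. On chromosomes 1 to 7, 11, X and Y and in the mitochondrial genome, between 0% and 1.84% of M21 genes had no row. On the remaining 11 autosomes the share ran from 9.57% on chromosome 8 to 40.6% on chromosome 13, where 1016 of 2502 genes had none. Protein-coding genes were affected little, with at most 3.43% without a row, on chromosome 10. In total 7478 of 55536 M21 genes had no row, among them 3010 processed pseudogenes, 2091 lincRNAs and 345 protein-coding genes. The names of 214 of these protein-coding genes were absent too. They included Vps28, which encodes a sorting complex subunit, Riok2, a ribosome assembly kinase gene, and the SNARE gene Vamp7, examples chosen after the list was seen. The symbol of a gene may have changed between releases, so an absent name does not exclude a row under another name. In the other direction, 382 of the 48440 mouse gene rows had an identifier that M21 does not hold. The table also held 3 reporter rows, Tdtomato, Egfp and Gfp, which are fluorescent protein genes, and the labels mention no reporter in these mice.

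**Figure D1:**
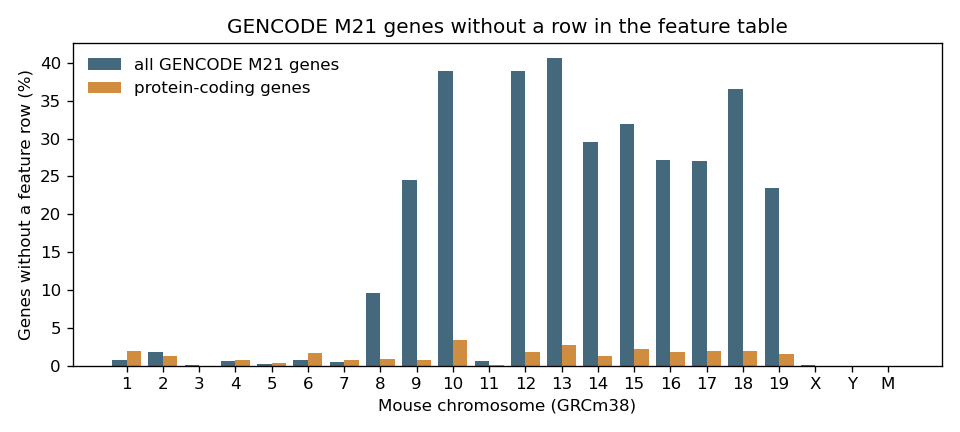
Share of GENCODE M21 genes without a row in the feature table (y axis, percent) by mouse chromosome (x axis, GRCm38), for all genes and for protein-coding genes. Chromosome X stands at 0.115% and 0%, and chromosome 13 reaches 40.6% of all genes but 2.75% of protein-coding genes. Genes on scaffolds are left out.

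The second question was how the droplet barcodes of the libraries related to each other. Library 3 listed 2506446 distinct barcodes and library 4 listed 3087873, with 0 repeated lines in either. The lists shared 1847376 barcodes. This was 73.7% of library 3 (95% Wilson interval 73.7% to 73.8%) and 59.8% of library 4 (59.8% to 59.9%). Random independent draws with this overlap would imply a pool of 4189503 barcodes (95% interval 4187539 to 4191466, counting error only). Counted as pairs that differ by complemented bases 8 and 9, whose members were not listed alike, the estimate was 3359875 pairs, or 6719750 barcodes if both members of every pair exist. Each library is a single list, so no spread between replicates could be set against the difference in list size. Base composition differed between the libraries by at most 0.295 percentage points at any position, with each base at 22.9% to 28.2%.

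Bases 8 and 9 of the barcode were tied to each other in both lists. Of 16 possible combinations only 4 occurred (AG, CA, GT and TC), each in 24.4% to 25.6% of barcodes. Complementing both bases turns AG into TC and CA into GT. In library 3, 19.5% of barcodes had this partner in the same list, and in library 4, 22.3%. At the other 12 neighbouring positions with any listed copy, the corresponding shares were 7.78% to 10.6% and 9.76% to 13.1%. How many changed copies exist as valid barcodes at each position is not given in the sources used here. The higher share at bases 8 and 9 is therefore not by itself an excess of listed partners. Complementing bases 7 and 8 or bases 9 and 10 gave no listed barcode, as the 4 allowed combinations require. Counted as pairs, library 3 listed at least 1 member of 2261809 pairs and library 4 of 2743322 pairs, and 1846756 pairs were in both. Both members were listed for 10.8% of the pairs in library 3 and 12.6% in library 4. Where each library listed 1 member of a shared pair, it was the same member in 1362079 of 1450050 pairs, or 93.9% (95% Wilson interval 93.9% to 94.0%).

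**Figure D2:**
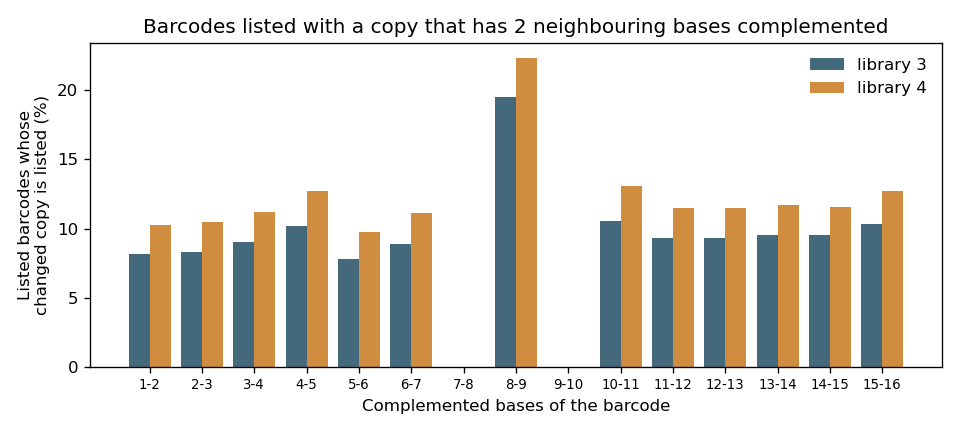
Share of listed barcodes (y axis, percent) whose copy with 2 neighbouring bases complemented is in the same list, by the positions complemented (x axis), for libraries 3 and 4. Positions 8 and 9 stand above the others at 19.5% and 22.3%, and the positions next to them are at 0%. The shares also depend on how many changed copies exist as valid barcodes at each position, which is unknown here.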

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

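The count of barcodes per library did not depend on whether repeated lines were counted, since there were none. Counting distinct names instead of rows gave 48333 features against 48452, and distinct identifiers gave 48452. Matching symbols without regard to case left 76 genes listed, and accepting other names, an alternative chosen after seeing the data, gave 78. The share of library 3 found in library 4 (73.7%) became 74.1% for barcodes that start with A or C, 73.3% for those that start with G or T and 73.6% in a random 10% of the barcode space. These 3 values lay outside the interval of the full list, though the wider interval of the random 10% itself (73.4% to 73.8%) holds the full list's value. The share of library 4 found in library 3 (59.8%) became 60.3% and 59.4% in the first 2 of these subsets and stayed within the full list's interval in the random 10%. Leaving out barcodes with a run of 4 or more equal bases kept both shares within the full lists' intervals. Counting pairs with complemented bases 8 and 9 once, also chosen after seeing the data, gave 81.6% and 67.3%. The estimated pool was then 3359875 pairs, or 6719750 barcodes if both members of every pair exist, 1.60 times the 4189503 estimated from single barcodes. A subset holds a smaller pool by construction: the estimate was 4138540 without runs, 2006943 for a first base of A or C, 2182740 for G or T and 419108 in the random 10%. The planned comparison of old with young, with its alternatives of normalization, filter and left-out animals, was not run, because no matrix values were analysed here. Depth limits could not be stated without molecule numbers.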

Other observations

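Of the tests and alternatives in this part, those of whole gene types, of pairs and of other gene names were chosen after the data had been seen. The others were chosen before their results were seen. On the assembled chromosome X, 3 M21 genes without a row leave 0.115% unlisted, against 39.0% on each of chromosomes 10 and 12. Genes on scaffolds, such as Vamp7, Tmlhe and Spry3, were counted with no chromosome. Any X-linked genes among them are not in these shares. Chromosomes 1 to 7 and 11 are nearly as full as X, from 0.139% unlisted on chromosome 3 to 1.84% on chromosome 2. The share of protein-coding genes without a row (0% on the assembled X, at most 3.43% on an autosome) is more even. What this does to a ratio of X-linked to autosomal signal was not measured.

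The genes without a row follow a simple rule. Of the 7478, 98.9% (98.850%) have an Ensembl gene number above the highest number in the table, and the other 86 lie on unplaced or unlocalised scaffolds, with 0 genes left over. No listed gene shared with M21 lies on a scaffold in M21, and where the identifier version differs it is older in 7452 genes and newer in 0. A candidate explanation is thus an annotation release older than M21, restricted to the chromosomes. A filter that removed whole gene types is argued against, since 0% of the genes without a row are of types with no row. Scaffold genes such as Vamp7 are outside the table. No biological explanation was tested.

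The partner barcodes with bases 8 and 9 complemented were weighed as a sign that barcodes of both bead oligo types, which differ at these bases in this chemistry, were listed without translation to 1 type. If partners arose in the same droplets, they would be in their own library's list more often than in the other's, once list size is taken into account. The ratio adjusted for list size was 1.0129 (jackknife SE 0.0009), inside the bounds of 5% to either side of 1 set beforehand. This argues against a tie within a library as the whole cause. The ratio was still above the 1.0007 to 1.0053 found at the other 12 neighbouring positions. Partners brought in by free molecules spread over many droplets stay open, because barcode lists without molecule numbers do not separate them.

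Barcodes that differ by 1 base occurred only at positions 10 to 16 and only as A-to-G or C-to-T exchanges in either direction. In library 3, 10.02% of barcodes had such a neighbour in the list, and in library 4, 10.01%. The same positions and exchanges held for neighbours in the other library's list. Neither they nor these shares therefore point to errors by themselves. Library 3 barcodes had their neighbour less often in their own list than in the longer list of library 4 (at base 10, 2.11% against 2.24%), and library 4 barcodes more often in their own (2.19% against 1.82%). Adjusted for list size, neighbours were in the own list more often, with a pooled ratio of 1.0721 (jackknife SE 0.0018) and 1.0614 to 1.0958 over the 7 positions. This is above the bound of 5% over 1 set beforehand and is consistent with base-call errors that turn one valid barcode into another. The ratio for single-base neighbours was not tested on simulated lists. Such errors may add empty barcodes to an unfiltered list. No biological explanation was tested.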
